A study of Mus musculus with 67 samples.

How the data were processed

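The libraries came from Iba1-positive regions of mouse hippocampus, captured with the GeoMx mouse whole transcriptome kit. Per the labels' protocols, fixed and paraffin-embedded tissue was cut at 4 µm. The design text adds that 3 hippocampal cores of 1 mm diameter were taken from every tissue block into a tissue microarray. How regions were chosen within the hippocampus, beyond the Iba1 label, is not given in the sources used here. Each library was 1 deposited file, and all came from 1 collection plate per the file headers.

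The deposited values were raw counts per probe tag, and the authors did not normalize them. Reads were processed with GeoMx NGS Pipeline 2.2.0.2 per the file headers, and the genome build was mm10 per the submitters' processing notes. The counts were well below the aligned reads, as when reads of one molecular identifier are collapsed: 1 minus the ratio of counts to aligned reads was 59.5% to 84.1%. Between 92.8% and 95.3% of raw reads aligned in each library except AD RACE PAM replicate 36, at 74.7%. Probes at 0 are left off the files' lists and were read as 0 (83 values). The step that joins probe tags to genes, and which probes are negative controls, are not given in the sources used here, so no background was subtracted. None of the probe IDs (0 of 20175) matched the RefSeq gene table at hand.

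Groups came from the sample titles, and replicate numbers are the library numbers in those titles. No number occurs in more than 1 group. The labels do not tie a region to an animal. With 3 cores per block, regions of a group can share an animal. P-values measure the spread between regions and are too small where regions of a group share an animal. All 581 pairs of libraries within a group differed by more than sampling noise (lowest chi-square over degrees of freedom 1.03, p = 0.00047, AD RACE PAM replicates 34 and 35), so this check found no repeated deposit of a library. It does not show that regions are independent, since separate regions of 1 animal would also differ by more than counting noise.

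Counts were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, trended dispersion, TMM scaling). The 66 libraries of the 4 groups with more than 1 library were fitted together, without covariates. Probes with at least 10 counts in at least 10 libraries were tested, which removed none of the 20175, and no library fell under the minimum of 10000 counts. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe was called at an adjusted p under 0.05. Fold changes are on the log2 scale with a standard error derived from the F statistic. CPM values are counts divided by the TMM-scaled library size, and log2 CPM used a prior count of 2.

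The text names, per comparison, up to 2 higher and 2 lower called probes with the largest fold change among those at or above the median mean log2 CPM. That rule, the tests and the settings to be compared were fixed before the data were examined. Gene lists for pathways and cell types had also been fixed, to be tested with limma's camera and fry where a table named the genes. They were not tested, because no table at hand did. Depth was compared by a two-sided permutation test with 100000 resamples, adjusted over the 4 comparisons.

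The fit was tested on simulated negative binomial counts for all 20175 probes, with 200 probes changed by 0.25, 0.5 or 1 on the log2 scale. Changes of 0.5 were recovered for 98.5% of probes in AD RACE PAM against AD NORACE PAM, 92.5% in AD NORACE PAM against Surveillant, 95.5% in AD RACE PAM against AD RACE NPAM and 91.0% in AD RACE NPAM against Surveillant. Changes of 1 were all recovered. Changes of 0.25 were recovered for 28.4%, 20.9%, 13.4% and 11.9% in the same order. Of 19975 unchanged probes, 4, 8, 6 and 6 were called. The simulation gives probes the trended dispersion and holds independent regions, so it does not cover probe-specific spread or shared animals.

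Other settings compared were upper quartile and total count scaling, DESeq2 1.42.0, limma-voom with upper quartile scaling (limma 3.58.1), no filter and a filter of 20 counts in at least 50% of the libraries, a fit of only the 2 groups compared, plate row or log2 total count as a covariate, quality limits of 80% aligned reads and 50% saturation, thinning to the 10th percentile of depth (338910 counts, 59 libraries kept), and leaving out each library. Added after the data were seen were a robust spread, an exact rank test, a fit without 5 libraries that stood apart on the first 5 principal components, the share of counts on the 200 most abundant uncalled probes as a covariate, plate row D alone, and comparisons within the plate rows that hold PAM and other regions. The AD NORACE NPAM group, with 1 library, entered no test.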

Results

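Gene expression was measured in captured regions of mouse hippocampus stained for Iba1, a marker of microglia, the resident macrophages of the brain. The assay was the GeoMx mouse whole transcriptome atlas, in which probes bind RNA in a tissue section and the tags of the probes within a region are collected and sequenced. The series concerns angiotensin converting enzyme (ACE) expression in microglia and amyloid deposition. Its labels sort the regions by genotype (AD or no AD, RACE or NORACE) and by a second term (Surveillant, PAM or NPAM). The labels do not spell out RACE, NORACE, PAM or NPAM, so these names are kept as given.

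The 67 libraries, each from 1 region, comprised 16 No AD NORACE Surveillant, 26 AD RACE PAM, 14 AD NORACE PAM, 10 AD RACE NPAM and 1 AD NORACE NPAM library. Each library listed counts for up to 20175 probes, and 20095 of these had at least 1 count in every library. The files pair no probe ID with a gene and none of the IDs matched the gene table used here, so results are given by probe ID. Levels of Ace and of pathway genes were therefore not analysed here.

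Total counts ranged from 137089 to 3176756 per library, with a median of 893813. They ran from 667695 to 3176756 in No AD NORACE Surveillant, from 177676 to 1679113 in AD RACE PAM, from 137089 to 1403445 in AD NORACE PAM and from 370252 to 1563577 in AD RACE NPAM libraries. The AD NORACE NPAM library held 532313 counts. Surveillant libraries were 2.10-fold deeper than AD NORACE PAM libraries by geometric mean (16 against 14 libraries, two-sided permutation test, p = 6.0e-05, adjusted p = 0.00024 over 4 comparisons). They were 1.68-fold deeper than AD RACE NPAM libraries (n = 10, permutation p = 0.0039, adjusted p = 0.0079). Depth did not differ detectably between AD RACE PAM and AD NORACE PAM libraries (log2 difference 0.06, permutation p = 0.85, adjusted p = 0.85) or between AD RACE PAM and AD RACE NPAM libraries (log2 difference -0.26, permutation p = 0.42, adjusted p = 0.56). Within a library the counts were flat across probes: the 99th percentile was 1.94 to 4.32 times the median count, with a median ratio of 2.48.

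**Figure D1:**
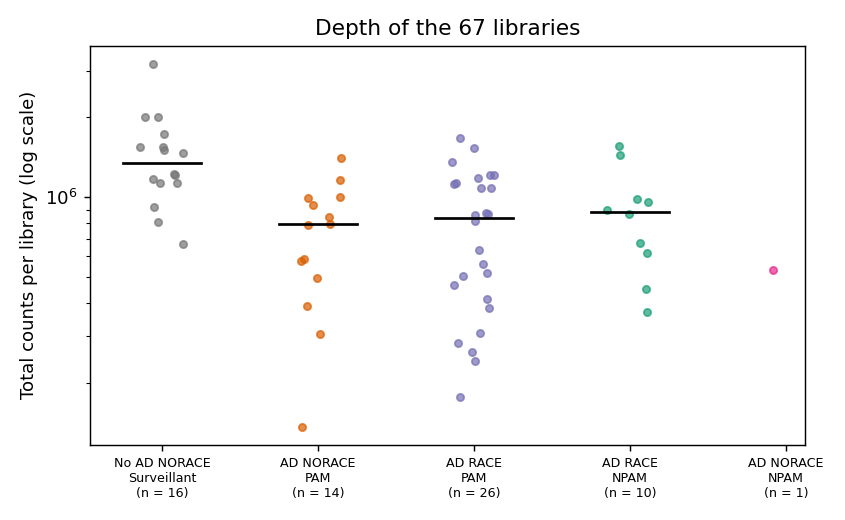
Total counts per library (log axis) for the 5 groups, 1 point per library, with a line at the median of each group that has more than 1 library. Surveillant libraries lie between 667695 and 3176756 counts, while AD NORACE PAM libraries reach down to 137089.

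The comparison of AD NORACE PAM with No AD NORACE Surveillant regions asked how regions of the AD genotype labelled PAM differ from regions without it. AD genotype and region type change together here and cannot be separated. Probe RTS0064807 was 3.42-fold higher in AD NORACE PAM regions, at 294 ± 138 CPM (SD, n = 14) against 85.8 ± 20.7 CPM (SD, n = 16), a log2 fold change of 1.77 ± 0.18 (SE; edgeR adjusted p = 1.9e-12). All 14 AD NORACE PAM libraries lay above the Surveillant median. With plate row as a covariate it was not called (log2 fold change 1.40). RTS0063209 was lower in AD NORACE PAM regions, at 110 ± 25.7 against 192 ± 78.9 CPM (log2 fold change -0.79 ± 0.16, edgeR adjusted p = 0.0012). RTS0063265 was also lower, at 46.5 ± 13.6 against 72.0 ± 37.6 CPM (log2 fold change -0.69 ± 0.15, edgeR adjusted p = 0.0055). For both probes 13 of 14 AD NORACE PAM libraries lay below the Surveillant median. The difference in RTS0063265 lay in Surveillant libraries of plate row A, at 59.3 to 182 CPM (n = 11), whereas those of row B held 28.5 to 44.6 CPM (n = 5), all below the AD NORACE PAM mean. With limma-voom and upper quartile scaling, the exact rank test and plate row as a covariate neither probe was called. Log2 fold changes under these were -0.70, -0.71 and -1.15 for RTS0063209 and -0.57, -0.49 and -0.44 for RTS0063265. RTS0063265 was not called after thinning (-0.58) or with a robust spread (-0.69) either. RTS0075419 had the largest fitted difference (log2 fold change 3.34 ± 0.48, edgeR adjusted p = 3.9e-07), and it rested on AD NORACE PAM replicate 47, with 18240 CPM where no other library of that group exceeded 704 CPM. Without that library its log2 fold change was 0.66 and it was no longer called.

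Across the 20175 probes, 114 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 82 higher and 32 lower in AD NORACE PAM regions. The called probes had a median log2 fold change of 0.42 among the higher and -0.36 among the lower, and 17 higher and 3 lower probes differed by more than 1.5-fold. The median over all probes was -0.01. With upper quartile scaling the split was 62 higher and 41 lower. The labels tie no region to an animal and the design text names 3 cores per tissue block. Regions of a group can therefore share an animal, and p-values over regions are too small where they do. Leaving out Surveillant replicate 13 raised the count to 270 and the share of counts on abundant probes as a covariate raised it to 246. Limma-voom with upper quartile scaling and the exact rank test each lowered it to 63, thinning all libraries to one depth lowered it to 26, and plate row as a covariate lowered it to 0 (1014 probes at an unadjusted p under 0.05), the groups having no plate row in common.

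The comparison of AD RACE PAM with AD RACE NPAM regions set 2 region types side by side within 1 genotype. RTS0064807 was 3.40-fold higher in PAM regions at 290 ± 101 CPM (SD, n = 26) against 86.3 ± 32.1 CPM (SD, n = 10), a log2 fold change of 1.76 ± 0.21 (edgeR adjusted p = 9.2e-10). RTS0080807 was 2.36-fold higher, at 213 ± 65.3 against 92.1 ± 33.7 CPM (log2 fold change 1.24 ± 0.19, edgeR adjusted p = 4.0e-06). For each of these probes 25 of 26 PAM libraries lay above the NPAM median. With plate row as a covariate neither was called (log2 fold change 1.69 for RTS0064807 and 1.25 for RTS0080807). RTS0065154 was lower in PAM regions, at 95.5 ± 18.2 against 142 ± 46.4 CPM (log2 fold change -0.61 ± 0.13, edgeR adjusted p = 0.0053), with all 26 PAM libraries below the NPAM median. Its call was lost without AD RACE NPAM replicate 67 (log2 fold change -0.53), with limma-voom and upper quartile scaling (-0.37), after thinning (-0.58), in the rank test (-0.50) and with plate row as a covariate (-0.25). RTS0065961 had the largest fitted decrease (log2 fold change -1.52 ± 0.24, edgeR adjusted p = 9.9e-06), resting on AD RACE NPAM replicate 62 at 3203 CPM; the other NPAM libraries held 104 to 184 CPM, and without replicate 62 its log2 fold change was 0.12.

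In this comparison 139 probes passed the threshold, 130 higher and 9 lower in PAM regions. The higher probes had a median log2 fold change of 0.49, and 35 of them were more than 1.5-fold higher. Regions within a group can share an animal, and p-values over regions are too small where they do. Regions of one animal can also be in both groups, which can act the other way, and no animal could be fitted. The count was 89, 91, 85 and 79 without AD RACE NPAM replicates 60, 62, 64 and 67, 34 after thinning to one depth and 32 in the exact rank test. With plate row as a covariate it was 1, a lower probe outside the 139, so 0 of the 139 were kept. The groups again had no row in common.

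The PAM comparisons of the 2 genotypes shared no library, and 32 probes were called higher in both, where 0.53 would be shared by independent lists of the same sizes among 20175 probes. A single probe was called lower in both (0.014 for independent lists), and 0 were called in opposite directions. These references take every probe as independent and equally likely to be called, so they are a loose guide. Both lists also came from the same fit, with a shared estimate of the spread. The 32 shared probes had a median log2 fold change of 0.57 in AD NORACE PAM against Surveillant regions (range 0.32 to 1.77) and of 0.56 in AD RACE PAM against NPAM regions (range 0.33 to 1.76). Of them, 20 were called in every fit that left out 1 library. Among the 114 probes called in the first comparison, 88 (77.2%) had the same sign in the second, 67 of the 82 higher and 21 of the 32 lower. Over all probes the fold changes correlated weakly (Pearson r = 0.13, Spearman rho = 0.04 across probes, which are not independent replicates).

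**Figure D2:**
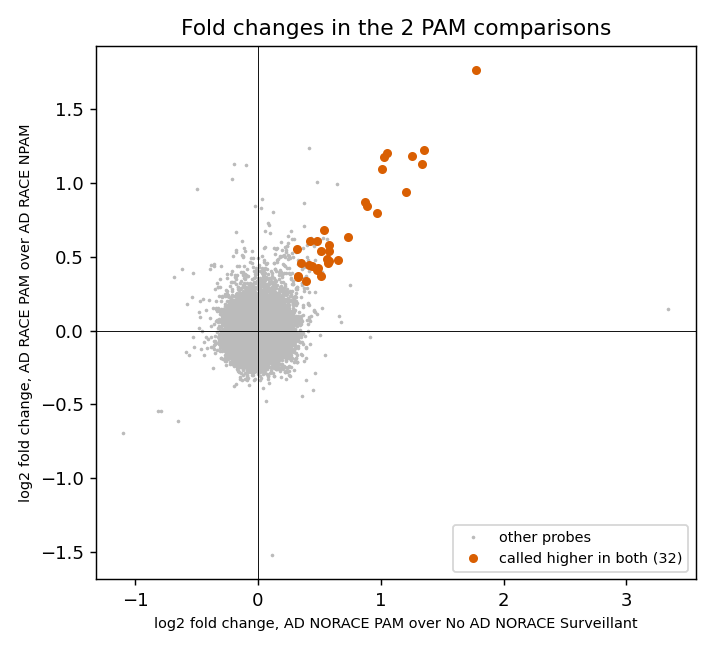
Log2 fold change of each probe in AD NORACE PAM over No AD NORACE Surveillant regions (x axis) and in AD RACE PAM over AD RACE NPAM regions (y axis), with the 32 probes called higher in both in orange and all others in grey. The orange points reach a log2 fold change of 1.77 on the x axis and 1.76 on the y axis.

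The mean log2 CPM of the 32 shared probes was 6.43 ± 0.24 (SD, n = 14) in AD NORACE PAM and 6.43 ± 0.29 (SD, n = 26) in AD RACE PAM libraries. It was 5.76 ± 0.15 (SD, n = 16) in Surveillant and 5.81 ± 0.14 (SD, n = 10) in AD RACE NPAM libraries. The probes were picked on these libraries, so these means describe them and are not a separate test. The single AD NORACE NPAM library, which took no part in picking the probes and has no replicate, stood at 5.76, within the range of 5.66 to 6.09 of the AD RACE NPAM libraries. Its level of RTS0064807 was 83.5 CPM.

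PAM and other regions lay together in plate rows B and E, which were compared after the data were seen, for 2 probes picked on these same libraries among others. In row B, RTS0064807 stood at 236 ± 137 CPM in AD RACE PAM (SD, n = 7) and 82.8 ± 6.63 CPM in Surveillant libraries (SD, n = 5), and 5 of the 7 PAM libraries exceeded every Surveillant library (exact permutation p = 0.039 on log2 CPM, adjusted p = 0.039 over the 2 rows). In row E it stood at 317 ± 163 CPM in AD NORACE PAM (SD, n = 9) and 107 ± 57.6 CPM in AD RACE NPAM libraries (SD, n = 3), with 8 of 9 above every NPAM library (exact permutation p = 0.0091, adjusted p = 0.018). RTS0080807 did not differ detectably in row B, at 176 ± 77.8 CPM in AD RACE PAM (SD, n = 7) and 158 ± 71.0 CPM in Surveillant libraries (SD, n = 5; exact permutation p = 0.80, adjusted p = 0.80). In row E it stood at 189 ± 58.1 CPM in AD NORACE PAM (SD, n = 9) and 102 ± 45.5 CPM in AD RACE NPAM libraries (SD, n = 3; exact permutation p = 0.05, adjusted p = 0.1). The genotype labels differ within both rows, the tests were two-sided, and p-values over regions are too small where regions share an animal. In both rows the groups filled separate runs of adjacent wells, so region type and position along the row were not told apart.

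**Figure D3:**
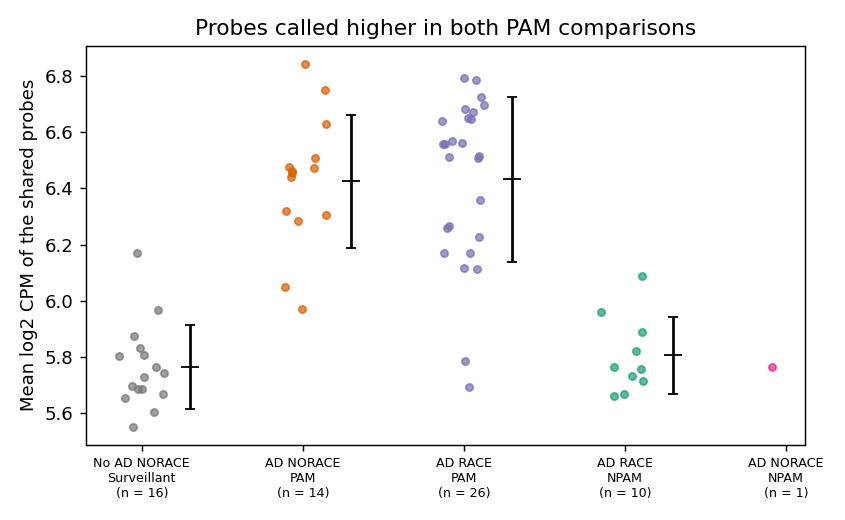
Mean log2 CPM of the 32 probes called higher in both PAM comparisons, 1 point per library, with the mean and SD of each group beside the points (no SD for the 1 AD NORACE NPAM library). Means are 6.43 in both PAM groups, 5.76 in Surveillant and 5.81 in AD RACE NPAM libraries.

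The comparison of AD RACE PAM with AD NORACE PAM regions addressed the RACE label within 1 region type. Of the 20175 probes 1 was called, RTS0075419, lower in AD RACE PAM regions by a log2 fold change of -2.64 ± 0.40 (edgeR adjusted p = 2.4e-05). Mean levels were 243 ± 211 CPM (SD, n = 26) and 1516 ± 4816 CPM (SD, n = 14), and the medians were 176 and 211 CPM. The difference came from AD NORACE PAM replicate 47: without it the log2 fold change was 0.04 (edgeR adjusted p = 1.00) and 0 probes were called, while leaving out replicate 57 gave 2. RTS0075419 was not called with DESeq2 (log2 fold change 0.09), limma-voom and upper quartile scaling (-0.53) or the exact rank test (-0.49); limma-voom called 0 probes, and DESeq2 and the rank test 1 each, not RTS0075419. Plate row as a covariate and leaving out the 5 libraries that stood apart gave 2 calls each, and the share of counts on abundant probes as a covariate gave 5. At an unadjusted p under 0.05 there were 1156 probes (5.73%). The SD of the fold changes over all probes was 0.10 on the log2 scale, close to their median SE of 0.09. In counts simulated for this comparison over 20175 probes, 98.5% of changes of 0.5 on the log2 scale and 28.4% of changes of 0.25 were recovered. Changes near 0.25 could thus mostly pass unseen at this depth and number of regions. These are changes in counts from which no background was subtracted, so they set no limit on changes in RNA of probes near background. The 7 AD RACE PAM and 5 AD NORACE PAM libraries in plate row D, the only row that held both groups, gave 2 calls, 1 in each direction, and the lower was RTS0075419 again (log2 fold change -3.44), with replicate 47 in that row. Regions of a group can share an animal here as well, and p-values over regions are too small where they do.

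**Figure D4:**
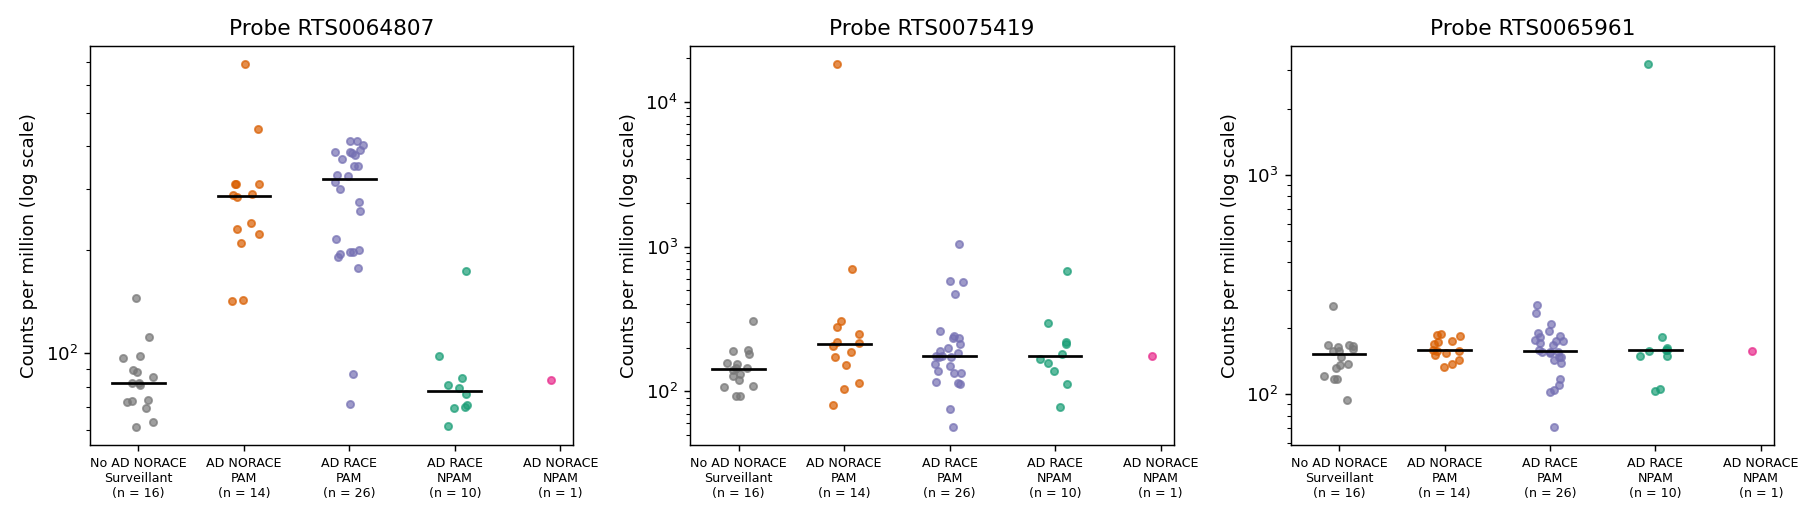
CPM per library (log axis) of probes RTS0064807, RTS0075419 and RTS0065961 in the 5 groups, 1 point per library, with a line at the median of each group that has more than 1 library. RTS0064807 is higher in both PAM groups, whereas RTS0075419 and RTS0065961 each have 1 library far above the others, at 18240 and 3203 CPM.

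The comparison of AD RACE NPAM with No AD NORACE Surveillant regions covered regions outside PAM, and both the AD and the RACE labels differ in it. RTS0075344 was 1.54-fold higher in AD RACE NPAM regions, at 227 ± 36.6 CPM (SD, n = 10) against 147 ± 26.1 CPM (SD, n = 16), a log2 fold change of 0.62 ± 0.13 (edgeR adjusted p = 0.012), with 10 of 10 libraries above the Surveillant median. This call was lost without AD RACE NPAM replicate 67 (log2 fold change 0.59), after thinning (0.50) and with a robust spread (0.62). Surveillant libraries held 134 ± 13.0 CPM in plate row A (SD, n = 11) and 177 ± 22.8 CPM in row B (SD, n = 5). RTS0072072 was lower, at 103 ± 63.9 against 225 ± 73.2 CPM (log2 fold change -1.13 ± 0.22, edgeR adjusted p = 0.0098), with 9 of 10 libraries below the Surveillant median. In a fit of the 2 groups alone, with plate row as a covariate and in the exact rank test it was not called (log2 fold change -1.13, -1.23 and -1.20), nor were RTS0075344 (0.62, 0.40 and 0.62) and RTS0063265 (-0.97, -0.67 and -0.81). RTS0063265, also lower in AD NORACE PAM regions, was at 37.0 ± 9.58 against 72.0 ± 37.6 CPM (log2 fold change -0.97 ± 0.17, edgeR adjusted p = 0.00082). That difference lay in Surveillant row A alone: row B libraries, at 28.5 to 44.6 CPM, fell within the 24.6 to 54.3 CPM of AD RACE NPAM libraries. RTS0065961 had a log2 fold change of 1.62 ± 0.27 (edgeR adjusted p = 0.00048) that rested on replicate 62 and was -0.03 without it.

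In all, 16 probes were called, 4 higher and 12 lower in AD RACE NPAM regions, and the same limit on p-values over regions applies. A fit of these 2 groups alone, plate row as a covariate and an exact rank test each called 0 (1494, 904 and 1549 probes at an unadjusted p under 0.05), and thinning left 5. DESeq2 called 41 among the 5312 probes to which it gave an adjusted p, and 10 of them were among the 16. Log2 total count as a covariate gave 38 calls and limma-voom with upper quartile scaling 26. The share of counts on abundant probes as a covariate gave 45, of which 18 were higher and 27 lower. The count was 10, 10, 8, 8 and 5 without Surveillant replicate 3 and AD RACE NPAM replicates 58, 60, 63 and 67, and 33 and 30 without AD RACE NPAM replicates 59 and 61.

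The last comparison asked whether probes that differed between AD NORACE PAM and Surveillant regions moved back or further in AD RACE PAM regions. The AD NORACE PAM libraries enter both fold changes with opposite sign, which alone gives a negative correlation. The observed value was -0.65 (Pearson r across probes; covariance -0.0076), and the mean of 20 simulations without any effect was -0.66 (covariance -0.0052), a difference in covariance of -0.0023. With the AD NORACE PAM libraries split at random so that no library was shared, the median correlation over 50 splits was -0.12 (range -0.19 to -0.05; Spearman rho -0.13; covariance -0.0021). The parts can still hold regions of the same animals or cores, and both are drawn from plate rows D and E. AD RACE PAM libraries also share row B with Surveillant and row D with AD NORACE PAM libraries. Shared rows can give a correlation without any RACE effect, and no simulation was run for the split value. The probes are not independent replicates, so the value carries no p.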

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

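The comparison within plate rows that hold both kinds of region, and the fit with the share of counts on abundant probes as a covariate, were chosen after the result was seen. Leaving out each library was planned, but the bounds by which it was read for RTS0075419 were set after that result was seen. Only AD RACE NPAM has between 4 and 10 libraries, so only there were single libraries compared with the rest by the gap to the nearest library over the whole range. Of 14 measures, 4 had a library farther out than chance gives in about 1 in 20 groups, and all 4 are probes named in the report. Most of the measures are named probes, some of them picked for large fold changes in comparisons that use this group. For those the rate of 1 in 20 is no fair reference. RTS0065961 stood at 3203 CPM in replicate 62, where the others held 104 to 184. RTS0064807 stood at 173 CPM in replicate 58, against 61.4 to 98.2. RTS0063209 stood at 46.2 CPM in replicate 59, against 115 to 304. RTS0072072 stood at 273 CPM in replicate 61, against 66.2 to 140 CPM.

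RTS0075419, the 1 probe called between AD RACE PAM and AD NORACE PAM regions, had a log2 fold change of 0.041 without AD NORACE PAM replicate 47, so the call came from that library. Why 1 probe was so high in it was not tested.

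The 32 probes higher in PAM regions of both genotypes are the pattern most open to follow-up. Lower depth of PAM libraries as the cause of the difference was not settled by thinning, which keeps the expected share of each probe. It can remove a fold change made by unequal counts in the fit, but not background tied to depth. Over 21 draws that thinned libraries to one depth, the median log2 fold change stayed at 0.875 or more of its value in both comparisons. In the first draw only 13 and 14 of the 32 probes were still called, with a median SE of 0.14 and 0.15. With log2 total count as a covariate, 52 probes were called higher in AD NORACE PAM against Surveillant regions, where 82 were without it. For AD RACE PAM against AD RACE NPAM there were 120 with it and 130 without it. An effect common to a whole plate row, as the only cause, is argued against by the rows that hold both kinds of region. There, 15 probes picked in the other rows were higher in PAM regions by 0.58 in row B (7 AD RACE PAM against 5 Surveillant libraries) and 0.65 in row E (9 AD NORACE PAM against 3 AD RACE NPAM libraries). Exact two-sided permutation p was 0.0366 and 0.0136, too small where regions share an animal or neighbouring wells resemble each other. Genotype labels differ within each row. Each group fills an unbroken run of wells in these rows, so position along the row was not told apart from region type. How much of the size came from row cannot be told apart. With row as a covariate the median log2 fold change was 0.46 and 0.63, or 0.802 and 1.11 of its value, with a median SE of 0.25 and 0.28 and 0 calls. The mean log2 CPM of the probes then differed by 0.40 ± 0.19 (SE) between AD NORACE PAM and Surveillant libraries, against 0.66 ± 0.09 without row. Between AD RACE PAM and AD RACE NPAM libraries it differed by 0.63 ± 0.20, against 0.63 ± 0.09. Rows A, C and F each hold a single fitted group, so the row-adjusted differences rest on libraries of rows B, D and E. They reuse the libraries compared within rows B and E and are not separate evidence. Stronger signal over background in PAM libraries may add to the difference and is left open. The 200 most abundant uncalled probes had a median log2 fold change of 0.02 and 0.14, the latter 0.252 of that of the 32 probes. The abundant share as a covariate left 0.983 and 0.974 of the value of the 32 probes. Both measures use uncalled probes only, so abundant probes called higher in PAM regions were removed beforehand. Low values therefore cannot count against this explanation. A difference between PAM and other regions, which the design names, stays open as a hypothesis.

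The number of calls was set against 100 random splits of the libraries of each comparison, the real one included. These splits treat regions as exchangeable and break up neighbouring libraries, which resemble each other, so they bear on chance among independent regions only and do not exclude a shared source such as an animal or plate position. For AD RACE PAM against AD RACE NPAM, 1 of 100 splits, the real one, gave as many as 139 calls and the highest other gave 4. So many calls were rare among random splits of regions, but 100 splits cannot show a share under 1 of 100. At an unadjusted p under 0.05, 2 of 100 gave as many as the real 1670 probes, with 1726 as the highest other. For AD NORACE PAM against Surveillant, 2 of 100 gave as many as 114, but the other of these called 857 probes, so the splits are a poor reference here, although their share is under 0.05. For AD RACE NPAM against Surveillant, 5 of 100 gave as many as 16, with 448 as the highest other, so chance cannot be excluded. For AD RACE PAM against AD NORACE PAM, 74 of 100 gave at least the real count of 1, with 5 as the highest other, and chance cannot be excluded. The splits with 857 and 448 calls point to a structure among the Surveillant libraries or those compared with them. In both, the mean share of counts on the 200 abundant probes differed between the sides, at 3.96% against 2.92% and 3.75% against 2.91%. Surveillant replicate 13, with the highest share in that group at 6.96%, lay on the high side in both, and without it the count for AD NORACE PAM against Surveillant was 270.

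The low count between AD RACE PAM and AD NORACE PAM regions could come from too few libraries or hide a shift of the PAM probes as a set. Too few libraries is argued against only for changes in counts near 0.5 on the log2 scale, with independent regions and the trended dispersion. Of simulated changes of 0.5, 98.5% were recovered, but 28.4% of changes of 0.25. Higher calls between PAM and other regions had medians of 0.42 and 0.49, so the smaller of them were not covered. AD RACE PAM against AD RACE NPAM, with fewer libraries, gave 139 calls, but 1, not among the 139, with plate row as a covariate. Its count does not measure recovery in this comparison. A shift of the set was looked for by picking the probes on one part of the libraries and comparing the held-out part. Over 100 such splits the median difference was 0.04 (the 5th to the 95th percentile, -0.16 to 0.24), with a median permutation p of 0.636 and p under 0.05 in 2 splits. That range comes from overlapping splits of the same libraries and is not a confidence interval. A shift within it cannot be told apart from none, and it does not exclude a larger one.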

How the results depend on the processing

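Alternatives named here as added were chosen after the data were seen. Counts are for AD RACE PAM against AD NORACE PAM (A), AD NORACE PAM against Surveillant (B), AD RACE PAM against AD RACE NPAM (C) and AD RACE NPAM against Surveillant (D), with counts of 1, 114, 139 and 16. Among 16, 15, 15 and 15 alternatives, 11, 9, 12 and 7 stayed within 1.5 times of these; the single call of A was another probe with DESeq2 and in the rank test. With limma-voom and upper quartile scaling, changed together, the counts were 0 in A (1263 probes at an unadjusted p under 0.05), 63 in B and 26 in D. With plate row as a covariate they were 2 in A, 0 in B, 1 in C and 0 in D (1014 and 904 probes at an unadjusted p under 0.05 in B and D). The 1 call in C was a lower probe outside the 139. No row holds both groups of B, C or D. The row-adjusted value of B thus rests on rows B and D, through AD RACE PAM libraries. That of C rests on rows D and E, through AD NORACE PAM libraries, and neither uses all libraries of its groups. For the 32 shared probes in C the median log2 fold change so obtained did not shrink (0.56 to 0.63) and the median SE rose from 0.12 to 0.28. Elsewhere a larger SE and smaller folds were not told apart. After thinning they were 26 in B, 34 in C and 5 in D, with fewer counts, and fewer libraries in the PAM groups only. DESeq2 gave 41 in D, among 5312 probes with an adjusted p. Log2 depth as a covariate gave 38 in D, and a fit of the 2 groups alone 0 in D (1494 probes at an unadjusted p under 0.05). Of the added settings, the exact rank test gave 63 in B, 32 in C and 0 in D (1549 probes at an unadjusted p under 0.05); leaving out the 5 libraries apart gave 2 in A and 270 in B; the abundant share as a covariate gave 5 in A, 246 in B and 45 in D; plate row D alone, 7 against 5 libraries, gave 2 in A. The cause was not tested except where stated. The 114 calls of B were all kept without the 5 libraries, which include replicate 13, and with the abundant share. Higher calls were 71.9% of B, but 60.2% with upper quartile scaling and 62.7% with log2 depth as a covariate. Higher calls were 25.0% of D, but 40.0% with the abundant share and 13.2% with log2 depth.

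Leaving out each library gave 0 to 2 calls in A (0 without replicate 47, 2 without 57), 83 to 270 in B (270 without 13), 79 to 186 in C and 5 to 33 in D. In every such fit 59 calls of B, 63 of C, 3 of D and 0 of A were kept. RTS0075419 in A reversed to 0.041 without replicate 47 (range -2.84 to 0.041 over left-out libraries) and to 0.094 with DESeq2. RTS0065961 in C reversed to 0.12 without replicate 62 (range -1.64 to 0.12), to 0.11 with DESeq2 and to 0.11 with plate row. RTS0065961 in D reversed to -0.026 without replicate 62 (range -0.026 to 1.74), to -0.012 with DESeq2 and to -0.29 with plate row. RTS0064807 kept its direction in B and C under all 15 alternatives and its call under 14, plate row ending it (log2 fold change 1.40 to 1.78 in B and 1.56 to 1.92 in C). The correlation of the RACE and AD fold changes was -0.12 under both scalings and the stricter filter, and the depth differences kept their side of the threshold with aligned reads. The filter removed no probe, so dropping it tested nothing. The gene list tests and their alternatives were not run, because no table at hand names the probes' genes. No paired analysis was possible because the labels tie no region to an animal, and the replicate numbers are library numbers. At the depth and number of regions here, changes of 0.25 on the log2 scale would mostly go uncalled.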

Other observations

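The test of neighbouring library numbers, and the look at single PAM libraries, were chosen after the data were seen. Among the 40 libraries of the PAM groups, 8 had a mean log2 CPM of the 32 shared probes at or below 6.17, the highest value of any Surveillant or AD RACE NPAM library. Of these 6 were AD RACE PAM and 2 AD NORACE PAM libraries. AD RACE PAM replicates 18 and 22 stood lowest, at 5.78 and 5.69, below the AD RACE NPAM mean of 5.81, with 71.4 and 87.2 CPM of RTS0064807 and 855888 and 633905 counts in all. No explanation for them was tested. The AD NORACE NPAM library had 256 CPM of RTS0075344 and 37.1 CPM of RTS0063265, where the AD RACE NPAM means were 227 and 37.0 CPM and the Surveillant means were 147 and 72.0 CPM. In Surveillant libraries of plate row B, RTS0063265 stood at 36.0 ± 5.78 CPM (SD, n = 5), the level of the NPAM libraries.

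Whether the PAM probes were also raised in AD RACE NPAM regions, compared with Surveillant regions, was posed as a hypothesis. With probes picked on part of the libraries and compared in the held-out part, the median difference over 100 splits was 0.12 on the log2 scale (the 5th to the 95th percentile, -0.03 to 0.24), with a median permutation p of 0.370 and p under 0.05 in 5 splits. The range holds both 0 and differences that would count, so the test leaves the question open.

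Libraries with neighbouring numbers resembled each other. Over the 2000 most abundant probes, the correlation of deviations from the group mean was higher between neighbours than between other pairs by 0.283 in Surveillant (one-sided permutation p = 0.0005, adjusted p = 0.001), 0.165 in AD RACE PAM (p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.0004) and 0.082 in AD NORACE PAM libraries (p = 0.0069, adjusted p = 0.0092). In AD RACE NPAM libraries the difference was -0.034 (p = 0.60, adjusted p = 0.60). A candidate explanation is that neighbouring numbers share a source such as a core, an animal or a plate position. The file headers give the wells, and library numbers follow well order, so neighbours mostly lay in adjacent wells. The labels name no core or animal, so plate position was not told apart from these. Shared sources within a group would make the p-values over regions too small.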
